A study of Homo sapiens with 12 samples.

How the data were processed

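Expression was measured on 6 Agilent whole human genome microarrays, each hybridised with a pair of labelled RNA samples, so that 12 labelled samples were read in 2 colours. The cells were H1, an established human embryonic stem cell line. Each of the 3 groups had 3 replicates, which the labels call independent. On the first 3 arrays RNA of butyrate-treated cells was labelled with Cy5 (red) and RNA of cells kept in conditioned medium with Cy3 (green). On the other 3 arrays RNA of cells returned from butyrate to conditioned medium was labelled with Cy5 and RNA of butyrate-treated cells with Cy3. No pair of groups was hybridised with the dyes exchanged.

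Per the file headers, the scanner files came from Feature Extraction A.7.5.1, while the submitters' processing notes name version 9.1. Each array's file was deposited under both of its labelled samples with identical values and was read here 1 time. Per the file headers, the spot intensity columns hold the mean signal and the local background median of each dye on a linear scale. The processed intensity of each dye had been corrected by the authors' software for a spatial trend and by lowess for the dyes, without subtraction of the local background and with substitute values for the dimmest spots, per the file headers. The deposited log10 ratio of Cy5 to Cy3 equalled the log10 ratio of the processed signals within 0.0001 for 96.4% of spots. The deposited table of the whole series holds a log2 value per probe and labelled sample. Its columns all had a median of 9.42 and the same quantiles. They correlated with log2 of the matching processed signal at 0.998995 or more. How they were equalised is not given in the sources used here.

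The main analysis started from the mean signals. Background was corrected with normexp (offset 50), and each array was normalised by loess over its 41675 non-control spots, with the 2256 control spots given no weight and left out afterwards. limma 3.58.1 in R 4.3.3 was used throughout, with data.table (version 1.17.8) for reading files and Python 3.11.15 with matplotlib 3.10.9 for the plots. Spots of 1 probe were averaged. A probe was kept if it was well above background on all arrays of at least 1 group, which left 37644 of 41000 probes. Of the 41000 probes, 21417 were named through their accession in the reference gene table, 2667 through their symbol and 1504 through an older symbol, and 15412 kept the name in the file. A gene with several probes was represented by its probe with the highest mean log2 intensity, and other probes that changed by less than 0.2 on the log2 scale, for a named gene whose used probe was called, are given beside it or after the lists. XIST and Y-linked genes were left out. This gave 28931 genes. Names kept from the file, among them clone and transcript names, count as genes here and in all counts of genes below.

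All 6 arrays were fitted in 1 limma model with a coefficient for each kind of ratio and 4 residual degrees of freedom. The first coefficient compares butyrate with conditioned medium and the second compares returned cells with butyrate. A gene whose dyes label unequally carries that bias in both ratios. Butyrate was Cy5 on 3 arrays and Cy3 on 3, so the first coefficient minus the second, divided by 2, compares butyrate with the mean of both groups in conditioned medium and cancels a constant dye bias; it is called the dye-balanced comparison. Returned and never-exposed cells did not share an array. They were compared with a separate-channel fit over all 12 labelled samples, with Aquantile normalisation between arrays, a term for the dye and an intraspot correlation of 0.608, over 28704 genes. P-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, and genes with adjusted p below 0.05 were called. Gene lists were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists with at least 5 measured members, and again with the correlation estimated from the data; members were also adjusted over the list alone.

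The comparisons, their tests, the 29 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per log-ratio comparison, the 8 genes that rose most and the 8 that fell most among called genes with the same sign on every array and in the separate-channel fit, with a gene symbol and a signal well above background on all arrays of the brighter group. It takes 4 each way for returned against never-exposed cells. POU5F1, NANOG, SOX2, DNMT3B, LIN28A and CDKN1A were named whatever their values, and up to 4 members of each list with the smallest p served as examples. Some genes that the rule takes are not reported here.

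A probe that was saturated on all arrays of a group has only a bound, and no fold is given for it. Precision is limited by the number of arrays. The median raw signal of non-control spots was 237 to 301 in Cy5 and 107 to 203 in Cy3. Between 92.4% and 94.6% of probes were well above background in Cy5 and between 83.7% and 91.6% in Cy3.

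The replicate numbers of the labels occur in all groups, so it was checked whether they pair the samples. The butyrate samples with the same number, read in Cy5 on 1 array and in Cy3 on another, deviated together from their group means across genes, with r of 0.430, 0.136 and 0.248 for replicates 1 to 3 after turning the sign. All were above the limit of 0.1 set for this check. Butyrate samples of different numbers gave -0.304 to 0.144, so the 0.136 of replicate 2 alone does not show a pairing. The fit with the replicate number as a block is therefore given only beside a result where it changes the call or moves a count of calls by over 1.5 times. Per the file headers, the arrays of butyrate against conditioned medium were extracted by the scanner software on day 1, those of returned replicates 1 and 2 on day 2 and that of returned replicate 3 on day 3, so that the day and the kind of ratio cannot be told apart; within-array ratios are less open to this than the comparison of returned with never-exposed cells.

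The scripts were tested on simulated data for 28742 genes. Simulated changes of 0.5, 1 and 2 on the log2 scale were recovered for 86.6%, 98.5% and 100% of genes in the dye-balanced comparison, 67.2%, 97.0% and 100% in butyrate against conditioned medium and 73.1%, 97.0% and 98.5% on return. In the separate-channel comparison of returned with never-exposed cells they were recovered for 0%, 22.4% and 93.9%. False calls numbered 20, 14, 7 and 11 in that order. The simulated noise was independent between arrays, without dye bias of single genes, pairing by replicate number or an outlying array. These figures are therefore not error rates of the real data. A simulated raised list was called by camera at an adjusted p of 5.05e-61, and 2 of 28 random lists were called as well. The random lists were drawn from all genes and could hold genes given a change, so these 2 are not certain to be false calls.

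Alternatives were no background correction, the processed log ratios, median centring, no filter and a stricter filter on dim probes, the mean of a gene's probes, the replicate block, a fit of only the 3 arrays of a comparison, the separate-channel fit, the series table, a variance trend with robust estimation and leaving out each array. Chosen after seeing the data were normexp on the background that the scanner software used, the brightest probe of a gene that was never saturated, and, for the lists and for the relation of the changes, leaving out conditioned medium replicate 2.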

Results

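H1 human embryonic stem cells were compared after 3 culture histories, each with 3 replicates. Cells of the first group were grown for 48 passages, the last 9 of them without feeder cells on the basement-membrane matrix Matrigel in medium conditioned by feeders. Cells of the second group moved to 0.2 mM sodium butyrate for passages 42 to 48. Butyrate is a short-chain fatty acid that inhibits histone deacetylases (HDACs). The butyrate medium held neither conditioned medium nor added bFGF, so this group differed from the first in both the drug and the growth support. Cells of the third group had butyrate for passages 42 to 46 and then conditioned medium with bFGF for passages 47 to 49. The treatment protocol in the labels counts 6 passages in butyrate for the second group, and 4 in butyrate and 3 in conditioned medium for the third, which is not the same count as the passage numbers. The question put to the arrays was how expression changed in butyrate and whether it returned when butyrate was withdrawn.

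The 6 arrays measured 28931 genes. Replicate arrays of returned cells over butyrate correlated across genes at r = 0.726 to 0.846. Those of butyrate over conditioned medium correlated at 0.264 to 0.691, and the lowest values, 0.264 and 0.489, involved the array of conditioned medium replicate 2. Its log2 ratios had an SD of 0.414, against 0.220 to 0.289 on the other arrays.

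Butyrate was first compared with the mean of both groups in conditioned medium, the comparison in which a constant dye bias cancels. LGALS1, which encodes the lectin galectin-1, rose most and was 6.56-fold higher (log2 2.71 ± 0.14). The antiviral membrane protein gene BST2 was 5.43-fold higher and SLC16A3, a transporter of lactate and other monocarboxylates, 5.11-fold higher. Dye-balanced values are given ± limma's SE, which borrows spread across genes and treats the 6 arrays as independent. The genes that fell most included LEFTY1, an inhibitor of NODAL signalling, which was 5.49-fold lower in butyrate (log2 -2.46 ± 0.11), and CXCR4, a chemokine receptor of definitive endoderm, which was 2.69-fold lower. Of 22 cholesterol synthesis genes 10 fell, and the list was lower by camera (adjusted p = 7.10e-05) but not called at an adjusted p = 0.402 with an estimated correlation. NANOG, SOX2 and LIN28A did not pass the test over all arrays, but NANOG and SOX2 were called lower without the array of conditioned medium replicate 2.

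By limma, 3479 genes were called, 1834 higher and 1645 lower in butyrate. Most changes were small: 91 genes were at least 2-fold higher and 21 at least 2-fold lower. With the replicate number as a block, 1581 genes were called. Leaving out conditioned medium replicate 2 gave 6286 and replicate 3 gave 2213, and leaving out returned replicates 1, 2 or 3 gave 1812, 1655 or 1846. Besides those above, the named genes that rose were GARIN1B (log2 2.67 ± 0.17), GDF15 (2.30 ± 0.14), a cytokine of the TGFB superfamily induced by cell stress, TBX1 (2.16 ± 0.11), a T-box transcription factor, and the placental lactogen genes CSH1 (2.29 ± 0.12) and CSH2 (2.20 ± 0.13). CSH1 and CSH2 are near-identical copies whose probes cannot be assigned with certainty, and the 4 probes of CSH1 ranged from 0.22 to 2.35 and a second CSH2 probe gave 0.56. Those that fell were the zinc finger gene ZIC2 (-1.57 ± 0.16), the glypican gene GPC6 (-1.42 ± 0.12), DUSP6 (-1.26 ± 0.05), a phosphatase of ERK, the secreted protease gene HTRA1 (-1.24 ± 0.13), SFRP2 (-1.21 ± 0.05), a secreted modulator of WNT signalling, and ID1 (-1.19 ± 0.06), a target of BMP signalling. A second GPC6 probe gave -0.03. The adjusted p-values of these 16 genes ran from 4.46e-05 for SLC16A3 to 0.00218 for HTRA1.

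**Figure D1:**
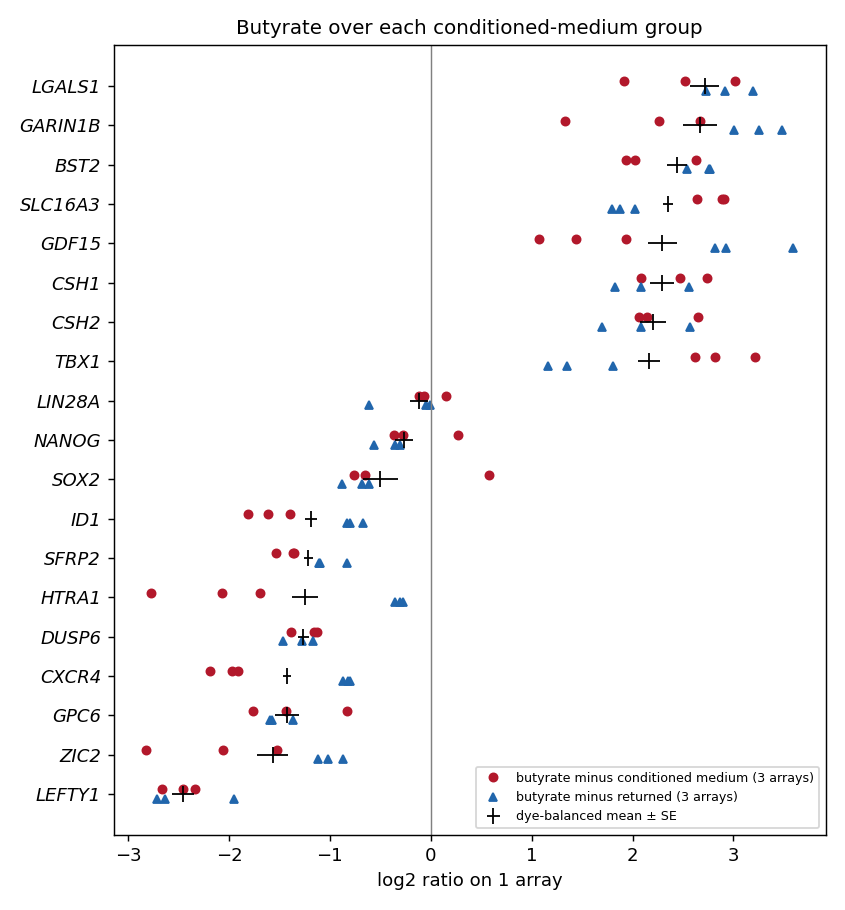
Each point is the log2 ratio on 1 array for the 16 genes with the largest dye-balanced changes and for NANOG, SOX2 and LIN28A; circles are butyrate minus conditioned medium, triangles butyrate minus returned cells (3 arrays each), and bars the dye-balanced mean ± SE. LGALS1 is at 2.71 and LEFTY1 at -2.46, and for NANOG, SOX2 and LIN28A the only point above 0 is that of conditioned medium replicate 2.

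Of 24 measured pluripotency genes, 3 rose, 1 fell and 20 did not pass the test, with the same counts when adjusted over the list alone. NANOG was at log2 -0.26 ± 0.09 (limma adjusted p = 0.133), SOX2 at -0.50 ± 0.18 (adjusted p = 0.145) and LIN28A, an RNA-binding protein of stem cells, at -0.12 ± 0.09 (adjusted p = 0.541); these p-values do not show that the genes were unchanged. Without conditioned medium replicate 2, NANOG (-0.36, adjusted p = 0.00267) and SOX2 (-0.71, adjusted p = 0.000303) were called lower. The separate-channel fit called both as well (adjusted p = 0.0263 and 0.0326), and the mean of its probes called SOX2 (adjusted p = 0.0436), whose second probe was at -0.47. LIN28A was called in none of 19 alternatives. DPPA2, a developmental pluripotency factor, rose by 0.49 ± 0.03. The probes used for POU5F1 and DNMT3B were saturated in every Cy5 sample, so no fold is given for either gene, though DNMT3B counts among the 3 that rose. The brightest POU5F1 probe that was never saturated was at -0.08 (adjusted p = 0.851). Of 12 genes associated with primed pluripotency, 1 rose and 5 fell, again with the same counts over the list alone, and the list was lower as a set (camera adjusted p = 0.00131). That call was lost at an adjusted p = 0.402 with an estimated correlation. ZIC2, SFRP2 and DUSP6 fell, as did HMGA2 (-0.55 ± 0.04), an architectural chromatin protein gene. Of 14 genes associated with naive pluripotency, 3 rose and none fell over all genes or adjusted over the list alone (camera adjusted p = 0.413). The largest was NLRP7 (1.41 ± 0.12). SUSD2 rose by 0.23 and KLF2 by 0.18, but with the replicate block their adjusted p-values were 0.0719 and 0.0687.

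Of 17 NODAL, ACTIVIN and TGFB pathway genes, 6 fell and 2 rose (9 and 3 when adjusted over the list alone; camera adjusted p = 0.0681). LEFTY1 and FST (-0.96 ± 0.07), which encodes the activin-binding protein follistatin, fell. INHBA, which encodes the activin A subunit, rose by 1.62 ± 0.06. Of 12 BMP targets, ID1, ID2 (-1.12 ± 0.13) and ID3 (-0.73 ± 0.11) fell and none rose, both over all genes and adjusted over the list alone (camera adjusted p = 0.0681). Of 20 FGF-ERK feedback genes and targets, 3 rose and 5 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.56), and DUSP6 was the largest change among them. Of 16 WNT targets, 3 rose and 3 fell on either adjustment (camera adjusted p = 0.702). FRZB (-0.63 ± 0.06) and SFRP2, both secreted WNT modulators, and the ligand WNT3 (-0.88 ± 0.11) fell, while the transcription factor TCF7 rose by 0.45 ± 0.05. The largest rise on this list, chosen after the values were seen, was AXIN2 (0.69 ± 0.11), a feedback inhibitor of the pathway, whose other probes gave 0.32 and -0.01.

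Among lineage lists, 6 of 19 endoderm genes fell and none rose (camera adjusted p = 0.0682), with the same counts adjusted over the list alone. Besides CXCR4 they included the transcription factor gene GATA6, which fell by 1.002 ± 0.123 and was well above background on 2 of 3 arrays of butyrate in Cy3. FOXA2 was at -0.43 (adjusted p = 0.0566 with the replicate block), and the 2 probes of GATA4 ranged from -0.38 to 0.01. Of 16 mesoderm and primitive streak genes, 4 fell, among them GSC (-1.01 ± 0.07), EOMES (-0.64 ± 0.05) and WNT3, and 2 rose, TBX1 and KDR (0.59 ± 0.07), the VEGF receptor; the counts were the same over the list alone (camera adjusted p = 0.56). Of 19 neural ectoderm genes, 2 rose and none fell (camera adjusted p = 0.768; the same adjusted over the list alone), led by NES (0.59 ± 0.07), an intermediate filament of neural progenitors. Of 22 trophoblast genes, 3 rose and 1 fell on either adjustment (camera adjusted p = 0.371), and ERVW-1, the fusogen syncytin-1, rose by 0.71 ± 0.04, though its second probe gave 0.01 and it was well above background on 2 of 3 arrays in conditioned medium. Of 18 germline genes, 3 rose and none fell on either adjustment (camera adjusted p = 0.369); MAGEA4 (0.17), PAGE4 (0.16) and TEX15 (0.22) had adjusted p-values of 0.129, 0.123 and 0.0860 with the replicate block. In conditioned medium MAGEA4 was well above background on 1 of 3 arrays and TEX15 on 2 of 3. Of 15 neuronal cytoskeleton, synapse and gap junction genes, NEFL (-0.46 ± 0.03) and DPYSL3 (-0.37 ± 0.05) fell and none rose on either adjustment (camera adjusted p = 0.927). Of 19 imprinted genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.781). GRB10, a signalling adaptor, fell by 1.14 ± 0.05 and PHLDA2 rose by 0.61 ± 0.09.

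Of 19 fibroblast and stromal cell markers, 6 rose and 1 fell on either adjustment (camera adjusted p = 0.166). The collagen genes COL1A1 (1.69 ± 0.12), COL1A2 (0.76 ± 0.11) and COL6A1 (0.68 ± 0.07) and the calcium-binding protein gene S100A4 (1.31 ± 0.10) rose. Second probes of COL1A2 and COL6A1 gave 0.05 and 0.04. Of 20 epithelial adhesion and EMT genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.625). The epithelial cadherin gene CDH1 rose by 0.84 ± 0.05 and the neural cadherin gene CDH2 fell by 0.53 ± 0.04.

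The list of genes known to respond to HDAC inhibitors had 5 of 20 members higher and 3 lower on either adjustment (camera adjusted p = 0.625). TXNIP, an inhibitor of thioredoxin, rose by 1.25 ± 0.06 and the placental-type alkaline phosphatase gene ALPG by 0.51 ± 0.06. CDKN1A, which encodes the cell-cycle inhibitor p21, rose by 0.37 ± 0.04 (adjusted p = 0.004). The nucleotide synthesis genes TYMS (-0.61 ± 0.05) and CTPS1 (-0.49 ± 0.05) fell. Of 18 HDAC and sirtuin genes, 2 rose and none fell on either adjustment (camera adjusted p = 0.748). HDAC1 rose by 0.54 ± 0.04, and SIRT1 was at 0.47 (adjusted p = 0.0968 with the replicate block). Of 17 DNA methylation and Polycomb genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0682). Besides the saturated DNMT3B they included the Polycomb protein gene CBX7 (0.56 ± 0.05), UHRF1 (0.51 ± 0.06), a partner of DNMT1 at hemimethylated DNA, and the DNA methyltransferase gene DNMT3A (0.46 ± 0.05).

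Cholesterol synthesis was the list with the most called members: 10 of 22 fell and 1 rose (11 and 1 adjusted over the list alone), and the list was lower as a set (camera adjusted p = 7.10e-05). With an estimated correlation the adjusted p = 0.402. MVK (-0.66 ± 0.04), CYP51A1 (-0.55 ± 0.05), ACAT2 (-0.53 ± 0.04) and DHCR7 (-0.41 ± 0.04), enzymes of the pathway, fell. Of 20 genes of fatty acid oxidation and butyrate use, 5 rose and none fell on either adjustment (camera adjusted p = 0.0681), among them ETFB (0.55 ± 0.05), an electron carrier of mitochondrial oxidation. Of 19 glycolysis and hypoxia genes, 3 rose and 2 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.748). The kinase gene PDK1 fell by 0.65 ± 0.09 and the lactate dehydrogenase gene LDHA by 0.53 ± 0.09. Few cell cycle genes moved: CCNB2, a mitotic cyclin gene, fell by 0.42 ± 0.03 with a second probe at 0.04, CCNE1 was at 0.31 (adjusted p = 0.0782 with the replicate block), and 22 of 24 did not pass on either adjustment (camera adjusted p = 0.795). Of 20 CDK inhibitors and p53 targets, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.37), with CDKN2D at 0.41 ± 0.03 and TP53I3 at -0.61 ± 0.05. Of 19 genes of the integrated stress response and UPR, 1 rose and 4 fell on either adjustment (camera adjusted p = 0.369). TRIB3, a pseudokinase gene, rose by 0.64 ± 0.07 with a second probe at 0.03. Of 12 heat shock genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.625), and the small chaperone gene HSPB1 rose by 0.55 ± 0.06. None of 12 metallothioneins passed on either adjustment (camera adjusted p = 0.781). Among control lists, 1 of 22 ribosomal protein genes rose (none over the list alone; camera adjusted p = 0.748) and 1 of 12 housekeeping genes rose on either adjustment (camera adjusted p = 0.768). That gene was B2M (0.93 ± 0.09), the invariant chain of MHC class I, whose second probe gave 0.02. No list was called with an estimated correlation. The separate-channel fit called 6 more lists, with endoderm (adjusted p = 0.0103), NODAL, ACTIVIN and TGFB pathway (0.0257) and BMP targets (0.00378) lower and fibroblast and stromal cell markers (0.0183), fatty acid oxidation and butyrate use (0.0257) and DNA methylation and Polycomb (0.0257) higher. Median centring called the NODAL and BMP lists too (0.0407 each). Other probes changed less than the one used for ALPG (0.08), CDKN1A (0.04), DNMT3A (0.15), DPYSL3 (-0.18), FOXA2 (-0.04), GSC (-0.12), HMGA2 (-0.13), KDR (0.14), KLF2 (0.02), MVK (-0.09), NEFL (-0.12), PDK1 (-0.06) and UHRF1 (0.13).

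**Figure D2:**
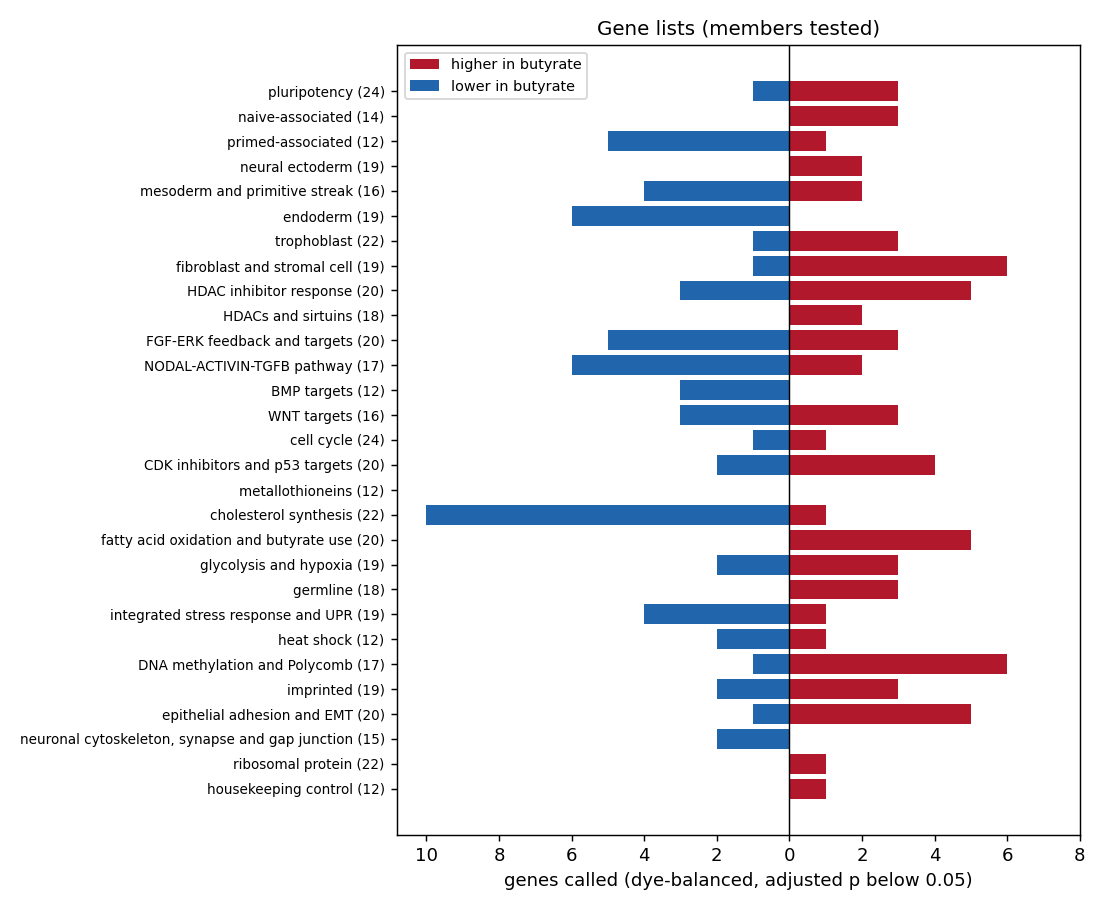
Bars show how many genes of each list were called in the dye-balanced comparison (limma adjusted p below 0.05), with genes higher in butyrate to the right of 0 and genes lower in butyrate to the left; the number of measured genes stands beside each list name. Cholesterol synthesis had 10 lower genes of 22, and the metallothioneins had none in either direction.

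Taken against never-exposed cells on the same arrays, genes higher in the butyrate group were among the largest changes of the series. CBR1, a carbonyl reductase gene, was 8.27-fold higher in butyrate (log2 3.05 ± 0.18, SD, n = 3), TBX1 was higher by 2.89 ± 0.30 and SLC16A3 by 2.81 ± 0.15. CTSF, a lysosomal cathepsin gene, was higher by 2.53 ± 0.23, LGALS1 by 2.48 ± 0.55, CSH1 by 2.43 ± 0.33 and the RNA helicase gene DDX43 by 2.38 ± 0.18. LEFTY1 fell by 2.48 ± 0.17, HTRA1 by 2.18 ± 0.55, ZIC2 by 2.13 ± 0.65, CXCR4 by 2.02 ± 0.15, the immediate-early transcription factor gene EGR1 by 1.92 ± 0.25, FST by 1.77 ± 0.23 and AK4, a mitochondrial adenylate kinase gene, by 1.65 ± 0.70; a second AK4 probe gave -0.31. DDX43 was well above background in conditioned medium on 2 of 3 arrays, and the probe of RPLP1 was saturated in Cy5 and has no fold.

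limma called 4068 genes, 2098 higher and 1970 lower, with 145 and 69 of at least 2-fold. The adjusted p-values of the named genes ran from 4.46e-05 for CBR1 to 0.00772 for AK4. With the replicate block 1476 genes were called, and with a dye term in the separate-channel fit 1262. CDKN1A was at 0.19 ± 0.13 (adjusted p = 0.104). NANOG was at -0.12 ± 0.35 (adjusted p = 0.562), SOX2 at -0.28 ± 0.74 (adjusted p = 0.503) and LIN28A at -0.01 ± 0.14 (adjusted p = 0.967). Without conditioned medium replicate 2, SOX2 moved to -0.70 (adjusted p = 0.00190), NANOG to -0.32 (adjusted p = 0.0241) and CDKN1A to 0.27 (adjusted p = 0.0236), and all were called. The second SOX2 probe was at -0.47 over all arrays. With median centring CDKN1A (0.62), NANOG (0.57) and LIN28A (0.50) were called higher, among 20220 called genes (12165 higher and 8055 lower). The count of called genes without conditioned medium replicate 2 was 6294 and without replicate 3 it was 2074; without returned replicates 1, 2 or 3, which enter only the shared spread, it was 2704, 2429 or 2661. With only the 3 arrays of this comparison in the fit it was 548.

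As sets, 6 lists were lower in butyrate by camera. These were primed-associated genes (1 of 12 higher and 4 lower, adjusted p = 0.0386), endoderm genes (none of 19 higher and 6 lower, 0.0287), BMP targets (none of 12 higher and 3 lower, 0.0352), FGF-ERK feedback genes and targets (1 of 20 higher and 3 lower, 0.0445), cholesterol synthesis (none of 22 higher and 6 lower, 0.000555) and ribosomal protein genes (2 of 22 higher and 9 lower, 0.000134). With an estimated correlation all 6 calls were lost, at an adjusted p = 0.432 for primed-associated, endoderm, BMP and ribosomal protein genes, an adjusted p = 0.603 for FGF-ERK and an adjusted p = 0.512 for cholesterol synthesis. Adjusted over the list alone, the counts differed from these only for cholesterol synthesis (2 higher, 9 lower) and ribosomal protein genes (2 higher, 11 lower). In the separate-channel fit with a dye term 3 of the 6 kept their call and endoderm (adjusted p = 0.0631), FGF-ERK (0.185) and ribosomal protein genes (0.972) lost it, while the pluripotency list was called higher (0.00552). Without conditioned medium replicate 2, primed-associated (0.0834) and endoderm genes (0.0944) lost theirs. The ribosomal list gave an adjusted p = 0.167 in the other direction when each gene was read from its brightest probe that was never saturated. With median centring in place of loess none of these 6 lists was called: cholesterol synthesis (adjusted p = 0.219) and ribosomal protein genes (0.191) turned direction, and the 5 lists that were called were all higher in butyrate.

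When cells went back to conditioned medium, LEFTY1 and DUSP6 rose and LGALS1, BST2 and GDF15 fell, each opposite to its change in butyrate. LEFTY1 rose 5.39-fold over butyrate (log2 2.43 ± 0.42, SD, n = 3), GPC6 by 1.51 ± 0.13 (0.03 for its second probe), DUSP6 by 1.30 ± 0.15 and the WNT receptor gene FZD5 by 1.29 ± 0.08. The methyltransferase gene TMT1A (1.25 ± 0.12), PLBD1 (1.22 ± 0.13), the myosin heavy chain gene MYH2 (1.18 ± 0.21) and SPATS2L (1.17 ± 0.05) also rose. GARIN1B fell by 3.25 ± 0.24, GDF15 by 3.11 ± 0.42, LGALS1 by 2.94 ± 0.23, BST2 by 2.69 ± 0.13 and CSH1 by 2.16 ± 0.37. EGR1, which was already lower in butyrate, fell by a further 2.47 ± 0.12. ANXA1, encoding annexin A1 (-2.66 ± 1.23), and ACTG2, encoding a smooth muscle actin (-2.23 ± 0.81), also fell, but these calls were lost with the replicate block, at adjusted p-values of 0.0849 and 0.101.

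limma called 2424 genes, 1144 higher and 1280 lower after return, with 38 and 103 of at least 2-fold. The adjusted p-values of the named genes ran from 0.00107 for EGR1 to 0.0171 for ANXA1. With the replicate block 427 genes were called and with the separate-channel fit 804, and within extraction day 2, without returned replicate 3, 484. Median centring called 19775, with 11299 higher and 8476 lower. CDKN1A fell by 0.54 ± 0.10 (adjusted p = 0.00637), and its second probe gave -0.13. That call was lost in 6 of 19 alternatives: the replicate block (adjusted p = 0.0647), the separate-channel fit (0.110), median centring (0.134) and without any 1 of the returned replicates (0.0510 to 0.0603). NANOG was at 0.40 ± 0.14 (adjusted p = 0.118), SOX2 at 0.72 ± 0.14 (adjusted p = 0.146) and LIN28A at 0.22 ± 0.34 (adjusted p = 0.363). NANOG and SOX2 were called higher on return in 3 of 19 alternatives each. These were the fit without conditioned medium replicate 2, which enters only the shared spread (adjusted p = 0.00544 and 0.000977), the fit of only the 3 arrays (0.00783 and 0.00177) and median centring (0.00350 and 0.00660), which also called LIN28A (0.00428). The second SOX2 probe was at 0.47. Without returned replicate 1 or 2 the count was 476 or 299, without conditioned medium replicate 2 it was 5942, and with only the 3 arrays of this comparison it was 7364. In leave-one-out fits the calls of GPC6 and MYH2 were lost as well, at adjusted p-values of up to 0.0585 and 0.0781.

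Of the lists, camera called primed-associated genes (5 of 12 higher and 1 lower, adjusted p = 0.00307) and cholesterol synthesis (5 of 22 higher and 1 lower, 0.00307) as higher after return. Fibroblast and stromal cell markers (none of 19 higher and 5 lower, 0.00307), naive-associated genes (1 of 14 higher and 2 lower, 0.0461), CDK inhibitors and p53 targets (1 of 20 higher and 6 lower, 0.00902) and ribosomal protein genes (1 of 22 higher and 10 lower, 7.14e-07) were lower. With an estimated correlation these calls were lost, at an adjusted p = 0.326 for primed-associated, p53 and ribosomal protein genes, an adjusted p = 0.328 for cholesterol synthesis and naive-associated genes and an adjusted p = 0.405 for fibroblast markers. Adjusted over the list alone, the counts were 9 higher and 1 lower for cholesterol synthesis, 1 and 8 for fibroblast markers, 1 and 3 for naive-associated genes, 1 and 8 for p53 targets and 1 and 11 for ribosomal protein genes; those of primed-associated genes were the same. In the separate-channel fit naive-associated (adjusted p = 0.118) and ribosomal protein genes (0.65) lost their call, and BMP targets (0.0486, higher) and fatty acid oxidation and butyrate use (0.0324, lower) gained one. The latter was also called without conditioned medium replicate 2 (0.0384). With probes that were never saturated naive-associated genes lost their call (0.0517). The ribosomal list turned direction with those probes (adjusted p = 0.387) and with median centring (0.325), as did CDK inhibitors and p53 targets with median centring (0.636). Median centring left 3 called lists, all higher on return, and of the 6 above only cholesterol synthesis (0.00252) was among them.

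Whether changes reverted was asked across genes. Of the 4068 genes called in butyrate against conditioned medium, 2507 (61.6%) moved the other way on return, and of the 214 that had changed at least 2-fold, 173 (80.8%) did. Both ratios contain butyrate samples of the same replicate numbers with opposite sign. The labels do not say whether these are the same RNA extracts, but their deviations correlated, and such a correlation makes the ratios oppose each other without any effect. Simulations without any effect, but with the mean correlation of these deviations, were run 100 times. Their genes were ranked by change relative to error, a choice made after the data were seen. Of the same number of top genes 70.4% moved the other way (58.8% of all genes). Of the 214 largest changes among these top genes, a mean of 72.5% moved the other way (64.0% to 79.4% over the simulations), against the observed 80.8%. The simulations held no dye bias of single genes, which moves both ratios the same way. Their top genes were also picked on noise alone, part of which both ratios share. The observed genes may hold real changes in butyrate. Neither the observed 61.6% nor the 80.8% can therefore be judged against the simulations. Across genes, which are not independent replicates, the ratios correlated at r = -0.224 with a covariance of -0.0124, against r = -0.273 and a covariance of -0.00252 in the simulations. Butyrate arrays set against returned arrays of other replicate numbers, whose butyrate samples have other numbers, gave a mean r of -0.161 and a covariance of -0.00995. Among genes called in both ratios, 591 rose in butyrate and fell on return, against 92.8 if the calls were independent and a mean of 232.1 in the simulations when as many genes each way were taken, and 396 fell and then rose, against 77.9 and 200.4. With median centring, which leaves the dependence of the dyes on brightness in both ratios, r was 0.693 and the share that moved the other way 7.71%. In the separate-channel fit that share was 81.3% and r was -0.127. Both comparisons of that fit use 1 butyrate estimate with opposite sign, and no share without effect was simulated for it. Another 222 genes rose in both ratios (83.0 if independent, 20.4 simulated) and 185 fell in both (87.2 and 20.7). The simulated overlaps and the simulated share of the 214 largest changes were added after the data were seen, and the overlaps leave out the error estimate that both tests share. The simulated overlaps, too, come from genes picked on noise alone. Part of the opposing excess may come from the butyrate samples common to both ratios.

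**Figure D3:**
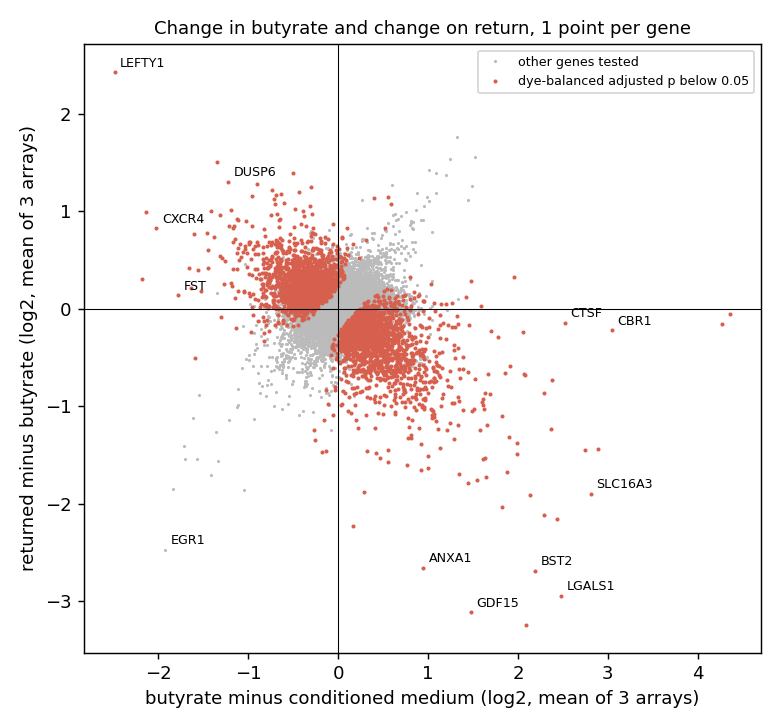
Each point is 1 gene, with the log2 change in butyrate against conditioned medium on the horizontal axis and the log2 change on return on the vertical axis (means of 3 arrays each); red points passed the dye-balanced test. LEFTY1 lies at -2.48 and 2.43, LGALS1 at 2.48 and -2.94, CBR1 at 3.05 and -0.22, and EGR1 at -1.92 and -2.47.

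Cells returned from butyrate were compared last with cells that had never been exposed. This asks how returned cells differed after 3 passages without butyrate, whether a difference remained from butyrate or arose on return. Returned cells were at passage 49 and never-exposed cells at passage 48, so passage number and butyrate history cannot be told apart. EGR1 was lower in returned cells (log2 -4.32 ± 0.27, SE) and was called lower in both ratios. ERVH48-1, a gene from an endogenous retroviral envelope, was higher (2.39 ± 0.23), as were CBR1 (2.12 ± 0.27), CTSF (1.91 ± 0.27) and RASIP1 (1.46 ± 0.18), a regulator of endothelial tube formation. CHCHD2, a mitochondrial protein gene, was lower (-1.82 ± 0.21), with all of its 4 probes lower in both ratios, and ADM, the vasoactive peptide adrenomedullin (-1.58 ± 0.24), and VARS2, a mitochondrial valyl-tRNA synthetase (-1.22 ± 0.18), were lower too. A second RASIP1 probe gave 0.01 in butyrate against conditioned medium, where the first gave 1.78.

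limma's separate-channel fit called 20 genes, 15 higher and 5 lower in returned cells; 2443 had an unadjusted p below 0.05. Adjusted p-values of the named genes ran from 3.39e-05 for EGR1 to 0.0402 for ADM. Other called genes, chosen after their values were seen, were NNAT (1.43), RBM46 (1.30), KLK8 (1.27) and NEFH (1.10). Entries without a gene symbol, which the naming rule leaves out, held the largest rises, 4.61 and 4.25 (limma adjusted p = 3.39e-05 and 1.27e-05). In butyrate against conditioned medium these entries were at 4.36 and 4.27. The replicate block gave 70 calls, and leaving out conditioned medium replicate 1 or returned replicate 1 gave 4, and leaving out returned replicate 2 or 3 gave 3. Of the 8 named genes only EGR1 kept its call in each of the 14 alternatives run. In the dye-included sum of both ratios 2031 genes were called. These groups never shared an array, so the comparison rests on brightness between arrays and its extraction days differed throughout. A simulated change of 1 on the log2 scale was recovered here for 22.4% of genes.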

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

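Normexp on the scanner software's own background, the brightest probe never saturated, and leaving out conditioned medium replicate 2 for the lists and the relation were chosen after the data were seen; the other alternatives were planned. All 16 named genes of the dye-balanced comparison kept direction and call in each of 19 alternatives. In butyrate against conditioned medium 13 of 16 kept their call and on return 12 of 16, all with the same direction. In returned against never-exposed cells 1 of 8 kept its call over 14 alternatives. For the log-ratio comparisons the naming rule required the same sign on every array and in the separate-channel fit. Direction therefore could not turn in that fit or without an array, and the rule took the largest called changes. Of 91 called list examples in the dye-balanced comparison, all kept direction, 60 kept their call in each alternative and 25 lost it with the replicate block. List examples are given for that comparison alone, a choice made after many examples of the single ratios were seen to turn direction. In butyrate against conditioned medium 24 of 106 examples, 89 of them called, did so in at least 1 alternative. On return 27 of 104 examples, 74 of them called, did so. Under median centring 19 turned in each. With the replicate block the counts of called genes were 1476, 427 and 1581 (1581 also by differences) for butyrate, return and the dye-balanced comparison, and 70 for returned against never-exposed cells; no list called in the text lost its call with it. Leaving out single arrays gave 2074 to 6294, 299 to 5942, 1655 to 6286 and 3 to 18 in the same order. Median centring, which moved the median of all genes from 0.02 to 0.13 and from 0.00 to 0.11 on the log2 scale, called 20220 genes in butyrate and 19775 on return, and 5 lists in butyrate, 3 on return and 4 in the dye-balanced comparison. It turned r to 0.693 and the share moving the other way to 7.71%, and in butyrate it turned LIN28A (0.50) and NANOG (0.57) upward; the saturated DNMT3B probe, whose readings give no fold, read 0.76. It turned the lists of cholesterol synthesis (adjusted p = 0.219), heat shock (0.0232) and ribosomal protein genes (0.191) in butyrate, and on return those of cell cycle (0.00943), CDK inhibitors and p53 targets (0.636), heat shock (0.0406) and ribosomal protein genes (0.325). With the brightest probe never saturated the ribosomal list turned in butyrate (0.167) and on return (0.387), and POU5F1 was at 0.16 in butyrate. Only the 3 arrays of a comparison gave 548 and 7364 genes. The separate-channel fit gave 1262 and 804 genes, 8 dye-balanced lists (4 in butyrate and 6 on return), a share of 81.3% and a reading of 1.03 for that saturated DNMT3B probe in butyrate. For returned against never-exposed cells the sum of ratios gave 2031 genes and no between-array normalization, which moved the median of all genes to -0.13, gave 4. No list was called with an estimated correlation (0 in each comparison), and fry called 17, 14 and 11. NANOG and SOX2 gained a call in 2 and 3 of 19 alternatives in the dye-balanced comparison, 1 each in butyrate and 3 each on return, and CDKN1A gained 2 in butyrate and lost 6 on return. Without conditioned medium replicate 2 the share moving the other way was 63.8%. The causes were not tested. Spots near background limit small changes most in Cy3, where 83.7% to 91.6% of probes were well above it.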

Other observations

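The tests of saturation, of the spread between probes over the other arrays and of stromal RNA were chosen after the result was seen. Genes that lay next to each other in the reference gene order had dye-balanced changes that correlated across 14590 pairs at r = 0.0975 (Spearman 0.0950), above the highest of 1000 shuffled orders (0.0260), and differences between replicate arrays, which hold no treatment, gave a median r of 0.0505. Genes well above background in every butyrate channel and in no other channel numbered 0, as did the reverse.

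The genes called lower on Cy5 in both ratios numbered 185, and 222 were called higher in both. Of the 185, 22 were read from a probe that was saturated in 1 dye on all arrays of a group. Of 22 ribosomal protein genes, 9 were called lower in butyrate and 10 on return. Saturation of the Cy5 channel may account for the ribosomal calls. Over 5 ribosomal protein genes without a saturated spot on any array the median of both ratios was 0.0464 (95% interval -0.189 to 0.253). It was -0.532 over the 17 with a saturated spot on at least 1 array. Unequal labelling of single genes by the dyes may account for part of the genes lower in both, since the fit with a dye term put the median difference of returned from never-exposed cells at -0.0832 over 184 of these genes, with a median dye term of -0.33. The probes used for EGR1 and CHCHD2, picked by their values, were not saturated on all arrays of any group. This argues against saturation throughout a group for them, though not against saturation on single arrays. The fit with a dye term gave them dye terms of -0.04 and -0.06 beside differences of -4.32 and -1.82. Both genes were picked by their differences in that same fit, which rests on brightness between arrays. A small dye term follows from that choice, so these values do not decide about dye bias.

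The array of conditioned medium replicate 2 differed from the rest. The SD between probes of the same gene was 0.576 on it, 3.46 times the highest of the other arrays (0.167), and on that array it was 4.91 times as large in Cy3 as in Cy5. These values are consistent with a fault in the RNA or labelling of the Cy3 sample, because a difference in the culture's expression would move the probes of a gene together. Which step was at fault, and whether that culture also differed biologically, stays open.

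Of 19 stromal markers 6 rose in butyrate and PDGFRB fell, while COL3A1 (0.02), COL5A1 (0.01), COL5A2 (0.03) and COL6A3 (0.09) did not pass the test. RNA of fibroblasts or other stromal cells could raise such genes, but it would raise the abundant matrix genes together, and the median of the 13 matrix members was 0.0295 (95% interval -0.00373 to 0.452), with 4 called higher and 0 lower. The interval ends below the median that was set as the mark of such cells. It also reaches above the value set to argue against them, so the test does not decide. COL1A1 rose by 1.69 and PDGFRB fell by 0.45. Expression of these genes by the butyrate-treated cells themselves was not tested.

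With 3 arrays there are 4 sign patterns for each ratio, and with 6 arrays or samples 10 splits, too few for a share under 0.05. In each comparison 1 pattern or split, the real one, gave its count, which was 4068, 2424, 3479 and 20 genes for butyrate, return, the dye-balanced comparison and returned against never-exposed cells, and the highest of the others was 0.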
